A study of Homo sapiens with 72 samples.

How the data were processed

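Human aortic endothelial cells of 12 donors were treated for 4 h with PAPC at 40 µg/ml or with OxPAPC at 20 or 40 µg/ml, 2 dishes each, and RNA was hybridised to 72 Affymetrix U133 Plus 2.0 arrays with 54675 probe sets, per the labels. The authors made the per-array files with Microarray Suite 5.0, per the series design text, and the submitters' processing notes name MAS5. The deposited per-array files hold, for each probe set, a Signal intensity on a linear scale, a Present, Marginal or Absent call and the deposited detection p-value behind it. The 2% trimmed mean of the Signal was between 2489 and 2493 on every array, so that the arrays had been scaled to a common level. The series value table holds the authors' intensity values on a linear scale, which the authors normalized with a median invariant method, per the series design text. Set against the Signal array by array, its log2 values correlated with r of 0.9986 or higher, 1 array was identical in both, the array medians were between 541.8 and 598.6, and 4 values were below 0. It is neither centred nor on a log scale. A scan date, slide or hybridisation batch was not given in the sources used here. The array numbers in the labels fall into ranges that hold 7, 4 and 1 donors, and 2 arrays have a number outside the range of their donor; these ranges served as a stand-in for batches.

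Probe sets were named through the platform annotation given for the series, with symbols updated through gene identifiers. Of the 54613 probe sets other than controls, 41091 had 1 symbol, 1801 several and 11721 none, and 41037 of those with 1 symbol matched the gene table. Probe sets with several or no symbols and sex-linked marker genes were left out. The Signal was taken as log2(Signal + 16) and quantile normalized over the 72 arrays, and differences are on that scale, which understates changes of dim genes. A probe set was kept if it was called Present on at least 8 of the 24 arrays of at least 1 treatment, which left 26192 probe sets. The probe set with the highest mean stood for its gene, which gave 11618 genes. Among 101 named genes 55 had another probe set, and for 7 genes changed at OxPAPC 40 another probe set had the opposite sign. For CYP26B1, called Absent on every OxPAPC 40 array, the fold is a bound from, per array, the higher of the lowest Present value and its own value.

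The dishes of a donor and treatment were averaged before the fit. The 36 means were fitted with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend), with treatment and donor as terms and Benjamini-Hochberg adjustment at 0.05. The donor term follows from the design, since each donor's cells received all treatments. As a check, the deviations of the same donor's means from the treatment means correlated with a median r of 0.68 (lowest 0.434), against -0.077 between donors. The donor-by-treatment interaction was an F-test of 22 coefficients on all 72 arrays with 36 residual degrees of freedom. Its error is the spread between dishes, so it says whether these donors differed as measured here. The labels show no repeat of a donor beyond the A and B dishes. A trait of the donor therefore cannot be told apart from variation between experiments. The letters H and L were compared with limma on 12 donor differences, and with exact permutation tests for CXCL8 and 15 list means. Gene lists (15 functional lists and 4 lists of smooth muscle, fibroblast, leukocyte and lymphatic markers) were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry, which tests whether the genes of a list move on balance in a direction without comparing them with other genes. Correlations over 12 donors used 100000 permutations, and those over 7 donors all orders (exact permutation).

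The samples, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule named, among genes past the threshold with the same sign in all 12 donors, the 12 largest rises and falls at OxPAPC 40, the 6 largest each way in the other comparisons, the 8 genes of smallest p for the interaction and for the letters, up to 4 members of each list by size of the statistic, and CXCL8. Other list members named in the text were chosen after their values were seen. Alternatives were median scaling, the series value table, offsets of 1 and 64, other filters, the mean of probe sets, single dishes, subsets of donors and arrays, each donor left out, eBayes without trend, no donor term, a random effect, and array number range as a block for the letters. A larger offset, 4 times the second alternative, and a fit without a PAPC array of low RNA quality were added after seeing the data. That array had the lowest share of Present calls (36.0%) and the highest 3' to 5' ratios of GAPDH (2.56) and ACTB (4.72) on the log2 scale. A list of LXR targets was also written after the data were seen and is reported among the other observations.

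The functions were tested on simulated data for 11618 genes with the spread of these arrays. For OxPAPC 40 against PAPC 40, 56% of genes changed by 0.25, 86% by 0.5 and 98% by 1 on the log2 scale were called. Each size was set in 50 genes. Of 11218 unchanged genes 74 (0.66%) were called, against 7 in each of the other comparisons of treatments. Next to the calls of changed genes, these 74 false calls were a larger share than the adjustment is meant to allow. The data had far more calls than the simulation had changed genes. The share of false calls in the data was therefore not estimated. For the letters, 80% of genes that differed by 1 and 98% that differed by 2 were called. For the interaction, 56% of genes with an SD of 0.25 between donors within each treatment and 98% with 0.5 were called. The deviations were drawn for each treatment, PAPC included, so that the donor differences from PAPC had a larger SD than these. Tables were read with pandas 2.3.3 and figures drawn with matplotlib 3.10.9 in Python 3.11.15.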

Results

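Primary human aortic endothelial cells (HAEC), the cells that line the aorta, were grown from 12 donors and exposed for 4 h to a phospholipid. PAPC (1-palmitoyl-2-arachidonoyl-sn-glycero-3-phosphocholine), the unoxidized lipid, was given at 40 µg/ml as the control. OxPAPC, the mixture formed when PAPC is oxidized, was given at 20 µg/ml and at 40 µg/ml. The cells of each donor received all 3 treatments in 2 dishes each, so that each treatment held 24 arrays and the series 72. Expression was measured on Affymetrix U133 Plus 2.0 arrays, and 11618 genes passed the filter on Present calls. The share of probe sets called Present was 42.0% ± 1.23 (SD, n = 12 donors) after OxPAPC 20 and 41.9% ± 1.41 after OxPAPC 40. The dishes of a donor and treatment correlated with r between 0.938 and 0.986 across genes. All 16 listed genes of endothelial identity, such as PECAM1, CDH5 and VWF, passed the filter. The number of donors and arrays limits the precision of the values. Unless stated otherwise, values are mean log2 differences over 12 donors.

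The first comparison asked which genes changed when the cells received OxPAPC rather than PAPC at the same mass of lipid, 40 µg/ml. OSGIN1, an oxidative stress response gene, had the largest rise of all genes that moved the same way in every donor, with a log2 difference of 3.92 ± 0.65 (SD of the donor differences, n = 12). It was called Present on 8 of the 24 PAPC arrays and all 24 OxPAPC 40 arrays, so that the size of its rise rests on values near background. Ranked by the probe set that stood for each gene, OSGIN1 was followed by the non-coding RNA LINC00304 with 2.97 ± 0.59 and by the stress-induced transcription factor ATF3 with 2.91 ± 0.72. The transcription factor KLF4 rose by 2.58 ± 1.05, tissue factor (F3, which starts coagulation) by 2.28 ± 0.99, and CHAC1, which degrades glutathione, by 2.14 ± 1.00. F3 was called Present on 7 of the 24 PAPC arrays. The small MAF protein MAFF rose by 2.10 ± 0.42 and the neutrophil chemoattractant CXCL8 (interleukin 8) by 2.10 ± 1.21, or by 3.15 ± 0.95 in a dimmer probe set. The brighter CXCL8 probe set stood at 16.43 ± 0.48 after OxPAPC 40, with a highest value of 16.72, so that its rise may be understated. The dimmer one would place CXCL8 above LINC00304. ZFAND2A (1.99), TRIB1 (1.98), the non-coding RNA LINC00622 (1.92) and KLHL21 (1.91) completed the 12 largest rises.

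The largest fall was that of CYP26B1, which breaks down retinoic acid. It was called Absent on all 24 arrays of OxPAPC 40 and Present on 21 of 24 after PAPC, so that its level is only bounded. The mean level was at least 14.0-fold lower. The measured donor differences ran from -5.95 to -2.32 on the log2 scale, so that the bound concerns the mean and not each donor. ENC1 fell by 2.23 ± 0.41 and CH25H, which makes 25-hydroxycholesterol, by 2.01 ± 0.53. TCIM fell by 1.87 ± 0.58, TNFSF10, which encodes the death ligand TRAIL, by 1.86 ± 0.58, and HOXA2 by 1.85 ± 0.51. The interferon-induced gene IFIT1 fell by 1.84 ± 1.09 and GJA5, which encodes the gap junction protein connexin 40, by 1.77 ± 0.77. PIK3R3 fell by 1.76 ± 0.48, FBXL15 by 1.67 ± 0.48, RNF145, a ubiquitin ligase of the sterol pathway, by 1.65 ± 0.41, and ASTE1 by 1.63 ± 0.86. On the 24 OxPAPC 40 arrays FBXL15 was called Present on 1, ASTE1 on 2, ENC1 on 5, IFIT1 on 7, CH25H on 12, HOXA2 on 15 and GJA5 on 16, so that the sizes of these falls also rest on values near background. The adjusted p of these 24 genes in limma ran from 2.11e-20 for OSGIN1 to 4.33e-07 for IFIT1.

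**Figure D1:**
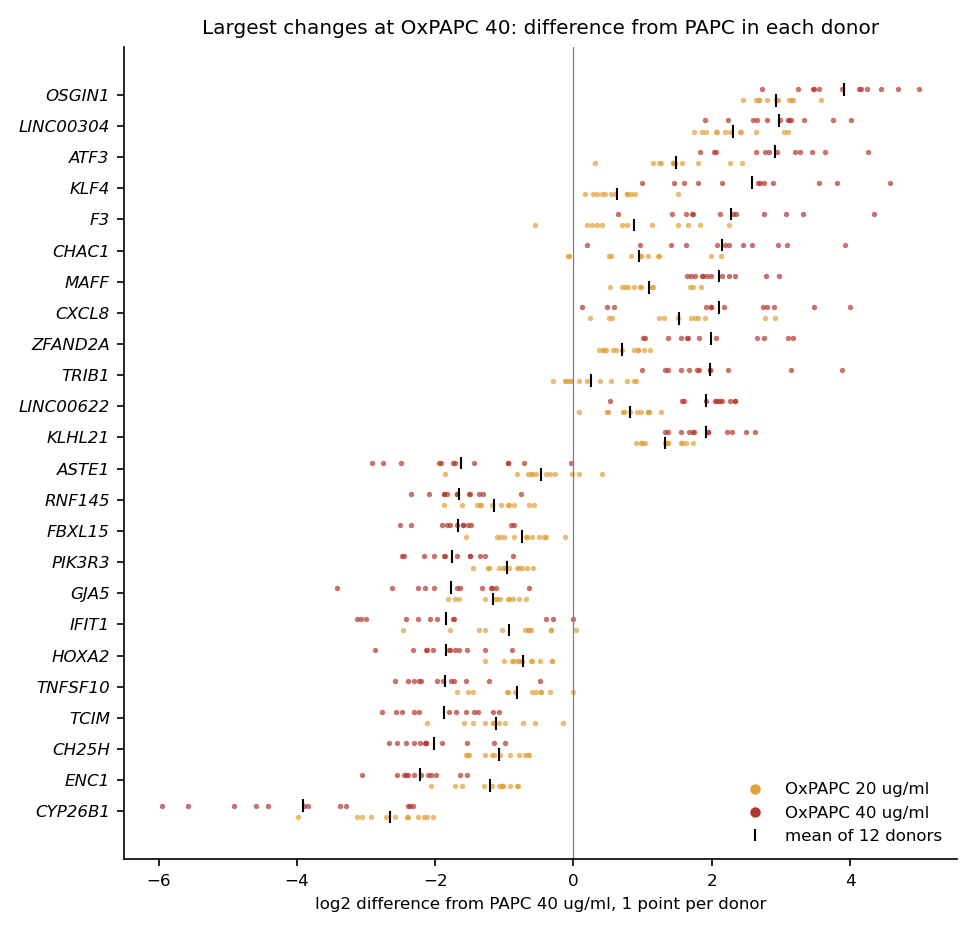
Log2 difference from PAPC 40 µg/ml on the horizontal axis for the 12 largest rises and 12 largest falls at OxPAPC 40 µg/ml, with 1 point per donor and a bar at the mean of 12 donors. At OxPAPC 40 all donors lie on the same side of 0 for each gene, from OSGIN1 with a mean of 3.92 to CYP26B1 with a measured mean of -3.91, and the means at OxPAPC 20 µg/ml lie nearer to 0.

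Of the 11618 genes, 2036 were higher and 3031 were lower at an adjusted p below 0.05 in limma with donor as a block, and 160 of them changed at least 2-fold. The difference had the same sign in all 12 donors for 1534 of the 5067 changed genes, and the median size of their change was 0.27 on the log2 scale. Without the donor term 951 genes were higher and 1047 lower.

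Genes of several stress responses rose at OxPAPC 40. Of the 19 tested targets of NRF2, the regulator of the oxidative stress response, 17 rose and none fell (camera adjusted p = 1.71e-18). They included SRXN1 (1.85 ± 0.06, SE), GCLM (1.24 ± 0.06), SQSTM1 (0.92 ± 0.04) and HMOX1, which breaks down heme (1.11 ± 0.09). The size of the HMOX1 rise is limited by a level near the highest on the arrays after OxPAPC. Another SQSTM1 probe set moved the other way (-0.31), while further ones rose by 1.72 and 1.30. Of 27 targets of ATF4, the regulator of the amino acid and integrated stress response, 20 rose and none fell (adjusted p = 4.77e-14, and adjusted p = 0.0519 with an estimated correlation). SLC3A2, a subunit of amino acid transporters, rose by 1.16 ± 0.06, PPP1R15A by 1.14 ± 0.07, SLC7A11 by 0.56 ± 0.04, and ATF4 itself by 0.84 ± 0.07. Of 9 heat shock chaperones 8 rose (adjusted p = 4.96e-08, and adjusted p = 0.0519 with an estimated correlation), with DNAJB1 at 1.67 ± 0.14, HSPH1 at 1.07 ± 0.07, BAG3 at 0.88 ± 0.07 and DNAJA1 at 0.86 ± 0.05. Of 15 immediate early and AP-1 genes 12 rose and EGR3 fell (adjusted p = 1.13e-06, and adjusted p = 0.0302 with an estimated correlation). Examples were DUSP1 (1.66 ± 0.14), FOSL2 (1.17 ± 0.09) and JUN (0.98 ± 0.06). Adjusted over the list alone, 21 ATF4 targets and all 9 heat shock chaperones were higher, 2 immediate early genes were lower, and the NRF2 counts were as above.

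Among 20 endoplasmic reticulum chaperones and folding enzymes, 7 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.0294, and adjusted p = 0.204 with an estimated correlation). The risers of over 0.5 were DNAJB9 (1.15 ± 0.07), the transcription factor XBP1 (1.08 ± 0.08), HERPUD1 (0.82 ± 0.05), a component of protein degradation, and the stress sensor ERN1 (0.70 ± 0.09). Another ERN1 probe set differed by -0.14. The abundant chaperones HSPA5 (0.06 ± 0.03, adjusted p = 0.141) and HSP90B1 (-0.04 ± 0.05, adjusted p = 0.546) did not pass the test, and CRELD2 fell by 0.23.

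Of 15 leukocyte-recruiting cytokines and adhesion molecules, 6 rose and 3 fell, also adjusted over the list alone, and the list did not pass the set test (camera adjusted p = 0.0536). CXCL8, CXCL3 (1.57 ± 0.22), CXCL1 (0.97 ± 0.12), IL1A (1.19 ± 0.24), ICAM1 (0.30 ± 0.07) and PTGS2 (1.47 ± 0.12), which makes prostaglandins, rose. The adhesion molecule VCAM1 fell by 1.12 ± 0.15, the monocyte attractant CCL2 by 0.68 ± 0.17 and the NF-kB inhibitor TNFAIP3 by 0.38 ± 0.10. Of 17 genes of sterol synthesis and uptake (SREBP2 targets), 10 rose and FDPS fell (adjusted p = 6.45e-04, and adjusted p = 0.204 with an estimated correlation), with the same counts adjusted over the list alone. INSIG1 rose by 1.24 ± 0.11, MSMO1 by 0.72 ± 0.09, SQLE by 0.61 ± 0.09 and SC5D by 0.24 ± 0.03. Another SQLE probe set differed by -0.005, while further ones rose by 1.02 and 0.62. Of 12 genes of the VEGF and hypoxia response, 8 rose and LDHA fell by 0.09, also adjusted over the list alone (adjusted p = 0.00427, and adjusted p = 0.105 with an estimated correlation). VEGFA rose by 0.98 ± 0.12 and NDRG1 by 0.49 ± 0.05. Of 11 coagulation and fibrinolysis genes, F3, PLAUR (0.50 ± 0.09) and SERPINE2 (0.19 ± 0.04) rose and THBS1 and PLAT (-0.17 ± 0.06) fell, with the same counts adjusted over the list alone (adjusted p = 0.444). Their median was -0.02 and their mean 0.20, and the sign of the median was the opposite in the series value table. PLAT did not fall in the 4 donors of the second array number range (0.09).

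Genes of the cell cycle and DNA replication fell. Of 24 tested, 23 were lower, also adjusted over the list alone (camera adjusted p = 1.13e-13, and adjusted p = 0.0519 with an estimated correlation). The mean of the list was below 0 in 12 of 12 donors. CDC20 fell by 0.74 ± 0.06, BUB1B by 0.71 ± 0.06, CCNA2 by 0.67 ± 0.05 and CCNB1 by 0.53 ± 0.04, while E2F1 differed by 0.10 ± 0.07. All 7 metallothionein and zinc export genes fell, also adjusted over the list alone (adjusted p = 1.65e-04, and adjusted p = 0.132 with an estimated correlation). The zinc exporter SLC30A1 fell by 1.19 ± 0.09, and the metal-binding MT1F, MT1E and MT1X by 0.55, 0.46 and 0.37. Of 16 genes of the type I interferon response, 9 fell and none rose, also adjusted over the list alone (adjusted p = 0.0294, and adjusted p = 0.204 with an estimated correlation). Beside IFIT1 these included IFIT2 (-0.98 ± 0.16, called Present on 6 of the 24 OxPAPC 40 arrays), IFIT3 (-0.75 ± 0.08) and IFI44 (-0.39 ± 0.06). The share of Present calls was itself lower at OxPAPC 40 than at PAPC 40, by 1.14 percentage points (two-sided exact sign-flip p = 0.0229, n = 12 donors).

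Of 13 flow-responsive and vasoprotective genes, 3 rose and 8 fell, and 9 were lower adjusted over the list alone (camera adjusted p = 0.0584). The list was not sorted by the direction of each gene's response to flow, so that these counts show neither a gain nor a loss of vasoprotection. The shear-induced transcription factors KLF4 and KLF2 (1.18 ± 0.15) and the growth factor ANGPT2 (0.30 ± 0.07) rose. The arterial connexins GJA5 and GJA4 (-1.36 ± 0.13), BMP4 (-1.58 ± 0.19) and the anticoagulant receptor THBD (-0.99 ± 0.18) fell. GJA4 and BMP4 were called Present on 9 and 10 of the 24 OxPAPC 40 arrays. Of 9 Notch signalling genes 5 fell, also adjusted over the list alone (adjusted p = 0.055), with HEY2 at -0.99 ± 0.08, NRARP at -0.50 ± 0.10, JAG1 at -0.38 ± 0.09 and JAG2 at -0.34 ± 0.05. Of 16 endothelial identity genes 5 fell, 3 adjusted over the list alone (adjusted p = 0.239). The transcription factor ERG fell by 0.44 ± 0.04 and ECSCR by 0.14 ± 0.05. ENG (-0.21 ± 0.04) and ROBO4 (-0.11 ± 0.04) fell too, although another probe set of each differed in the other direction, by 0.31 and 0.11, and their mean over probe sets was 0.051 and 0.00414.

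Of 10 smooth muscle markers 4 were tested, and ACTA2 fell by 0.10 ± 0.04, while SMTN (0.15) and ACTG2 (-0.03) did not pass the test. Of 11 fibroblast markers 7 were tested, and COL1A1 (-0.29 ± 0.11) and POSTN (-0.22 ± 0.06) fell, each with another probe set of opposite sign. Of 11 leukocyte markers 2 were tested, LAPTM5 (-0.02) and CD79A (0.05), and neither passed. Of 6 lymphatic markers 3 were tested, of which RELN (0.68 ± 0.13) and LYVE1 (0.45 ± 0.18) rose and PROX1 (-0.62 ± 0.14) fell. The median level of these 3 after PAPC was 9.855, at the 15.6th percentile of the tested genes. With a filter of Present on 60 of 72 arrays 0 of them remained, so that these changes rest on dim values. In the A dishes alone LYVE1 differed by -0.12. The camera adjusted p of these 4 lists was 0.577 or higher, and the fibroblast markers had a median of 0.0052 and a mean of -0.04. Adjusted over the list alone, ACTA2 and 1 of the fibroblast markers no longer passed. Of all lists at OxPAPC 40, 10 passed camera, and 2 of these, the NRF2 targets and the immediate early genes, held with an estimated correlation. Under median scaling 13 passed camera, the leukocyte-recruiting, flow-responsive and Notch lists among them. The same lists also passed with no filter and in the A dishes alone, so that at the preset correlation their misses depend on the setting. With an estimated correlation the adjusted p of these 3 lists, in the order given, was 0.295, 0.111 and 0.226. Fry, which makes no comparison with other genes, gave an adjusted p of 8.49e-04, 1.24e-09 and 6.84e-06. The tests thus disagreed on these lists.

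**Figure D2:**
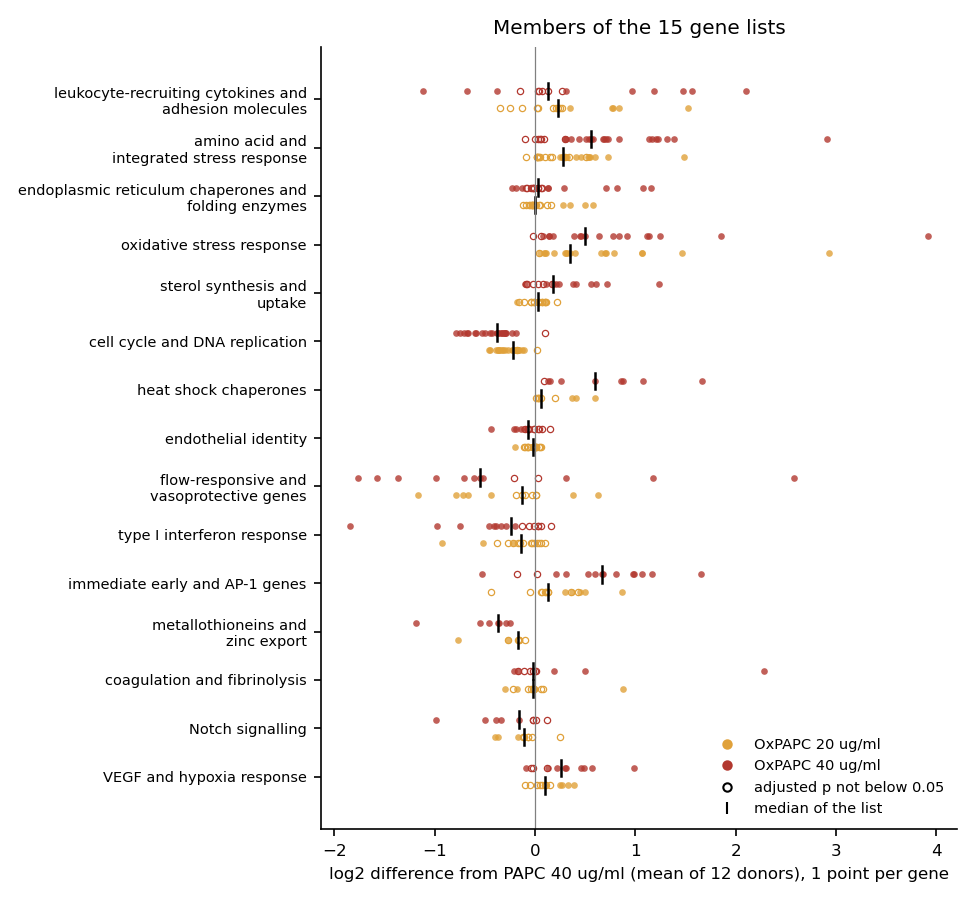
Log2 difference from PAPC 40 µg/ml, as the mean of 12 donors, on the horizontal axis for each tested member of the 15 gene lists at OxPAPC 20 and 40 µg/ml; filled points passed an adjusted p below 0.05, open points did not, and bars are the medians of the lists. The NRF2 targets (oxidative stress response) lie to the right with medians of 0.35 and 0.50, and the cell cycle genes to the left with medians of -0.22 and -0.38.

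The second comparison set OxPAPC at 20 µg/ml against PAPC at 40 µg/ml, so that both the mass and the oxidation of the lipid differed. OSGIN1 again had the largest rise, of 2.92 ± 0.30 (SD, n = 12), followed by LINC00304 with 2.31 ± 0.44, CXCL8 with 1.52 ± 0.83, ZNF442 with 1.49 ± 0.69, ATF3 with 1.49 ± 0.54 and the antioxidant enzyme SRXN1 with 1.46 ± 0.18. The dimmer CXCL8 probe set rose by 2.06 ± 0.65. ZNF442 was called Present on 3 of the 24 OxPAPC 20 arrays and 2 of the 24 PAPC arrays, and CYP26B1 and ENC1 on 6 and 14 of the OxPAPC 20 arrays, so that the sizes and ranks of these changes rest on values near background. CYP26B1 had the largest fall, of 2.65 ± 0.56, followed by ENC1 (-1.21 ± 0.39), GJA5 (-1.17 ± 0.37), RASSF10 (-1.15 ± 0.76), RNF145 (-1.15 ± 0.39) and TCIM (-1.12 ± 0.50). In all, 812 genes were higher and 881 lower at an adjusted p below 0.05 in limma, and 28 changed at least 2-fold. Higher calls made up 48.0% of the changed genes, and 58.8% when the arrays were scaled to a common median. Without the donor term 104 genes were higher and 41 lower.

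At this dose the NRF2 targets had already moved, with 18 of 19 higher, also adjusted over the list alone (camera adjusted p = 3.76e-35). HMOX1 stood at 1.06, GCLM at 1.07 and AKR1C1 at 0.79. The HMOX1 level was 16.20 ± 0.44 (SD, n = 12) after PAPC and 17.26 ± 0.04 after OxPAPC 20, where the highest value on an array was 17.65 on average. Of the 27 ATF4 targets 14 were higher, 17 adjusted over the list alone (adjusted p = 1.25e-12, and adjusted p = 0.078 with an estimated correlation). Of the 24 cell cycle genes 22 were lower, 23 adjusted over the list alone (adjusted p = 5.89e-17, and adjusted p = 0.0334 with an estimated correlation). Of the 15 leukocyte-recruiting genes 5 were higher, and 2 were lower adjusted over the list alone (adjusted p = 0.00308, and adjusted p = 0.162 with an estimated correlation). Of the 17 SREBP2 targets SC5D was higher and HSD17B7 lower, also adjusted over the list alone (adjusted p = 0.543), and INSIG1 stood at 0.22. Of the 13 flow-responsive genes 2 were higher and 5 lower, also adjusted over the list alone (adjusted p = 0.0379, and adjusted p = 0.078 with an estimated correlation). Of the 9 Notch signalling genes 3 were lower, 4 adjusted over the list alone (adjusted p = 0.0449, and adjusted p = 0.235 with an estimated correlation). The heat shock chaperones (3 of 9 higher, adjusted p = 9.05e-04, and adjusted p = 0.195 with an estimated correlation), the immediate early genes (5 of 15 higher, adjusted p = 4.23e-04, and adjusted p = 0.078 with an estimated correlation), the VEGF and hypoxia genes (4 of 12 higher, adjusted p = 0.0258, and adjusted p = 0.184 with an estimated correlation), the metallothioneins (2 of 7 lower, adjusted p = 2.53e-04, and adjusted p = 0.162 with an estimated correlation) and the interferon genes (3 of 16 lower, adjusted p = 0.0398, and adjusted p = 0.242 with an estimated correlation) passed camera too. Adjusted over the list alone, 4 heat shock chaperones and 4 VEGF and hypoxia genes were higher, and 6 metallothioneins, 1 VEGF and hypoxia gene and 1 immediate early gene were lower.

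The third comparison, OxPAPC 40 against OxPAPC 20, asked what the higher dose added. KLF4 was higher by 1.95 ± 0.87 (SD, n = 12), TRIB1 by 1.72 ± 0.62, ATF3 by 1.43 ± 0.62, the protease ADAMTS1 by 1.42 ± 0.42, F3 by 1.41 ± 0.38 and ZFAND2A by 1.28 ± 0.64. BMP4 was lower, at -1.44 ± 0.82, as were the LDL receptor ligase MYLIP (-1.19 ± 0.57), ASTE1 (-1.16 ± 0.69), HOXA2 (-1.12 ± 0.58), ZNF792 (-1.09 ± 0.55) and PAGR1 (-1.03 ± 0.44). ASTE1, ZNF792, PAGR1 and BMP4 were called Present on 2, 4, 8 and 10 of the 24 OxPAPC 40 arrays, and F3 on 14 of the 24 OxPAPC 20 arrays. In all, 1061 genes were higher and 1444 lower at an adjusted p below 0.05 in limma, and 25 changed at least 2-fold. Without the donor term 222 genes were higher and 160 lower.

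Of the heat shock chaperones 8 of 9 were higher at 40 than at 20 µg/ml (camera adjusted p = 1.66e-10, and adjusted p = 0.0226 with an estimated correlation), as were 18 of 27 ATF4 targets (adjusted p = 1.59e-11, and adjusted p = 0.107 with an estimated correlation). Of the SREBP2 targets 7 of 17 were higher (adjusted p = 2.41e-06, and adjusted p = 0.107 with an estimated correlation), with INSIG1 at 1.01, MSMO1 at 0.69 and HMGCS1 at 0.54. Of the immediate early genes 8 of 15 were higher and IER3 lower (adjusted p = 5.16e-07, and adjusted p = 0.0226 with an estimated correlation). Of the NRF2 targets 8 of 19 were higher (adjusted p = 3.81e-06, and adjusted p = 0.00873 with an estimated correlation), and AKR1C1 differed by -0.01, short of the threshold. HMOX1 stood at 17.31 ± 0.03 (SD, n = 12) after OxPAPC 40, near the highest value on the arrays, and no dose difference is read from it. Of 24 cell cycle genes 17 were lower (adjusted p = 3.79e-08, and adjusted p = 0.111 with an estimated correlation). The metallothioneins (6 of 7 lower, adjusted p = 0.00261, and 0.215 with an estimated correlation) passed camera too. So did the endoplasmic reticulum list (4 of 20 higher and 1 lower, adjusted p = 0.0145, and 0.159) and the VEGF and hypoxia genes (4 of 12 higher, adjusted p = 0.0145, and 0.147). PTGS2 (1.21) and CXCL3 (0.73) were higher and CCL2 (-0.86) and VCAM1 (-0.77) lower, and the leukocyte-recruiting list as a whole did not pass (adjusted p = 0.628). CXCL8 was 1.10 ± 0.73 (SD, n = 12) higher in its dimmer probe set, and in 11 of 12 donors. The brighter one stood at 15.85 ± 0.88 after OxPAPC 20 and 16.43 ± 0.48 after OxPAPC 40, with highest values of 16.79 and 16.72, and no dose difference is read from it either. Adjusted over the list alone, the counts higher were 8 heat shock chaperones, 20 ATF4 targets, 7 SREBP2 targets, 9 immediate early genes and 10 NRF2 targets, and 19 cell cycle genes were lower. The endoplasmic reticulum list then had 5 higher and 1 lower, and the metallothionein and VEGF counts were as above.

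Across genes, which are not independent replicates, the differences from PAPC at 20 and 40 µg/ml correlated with r = 0.82. The same PAPC dishes served both, and simulated treatments with no effect gave r = 0.501. With the A dishes of PAPC for 40 µg/ml and the B dishes for 20 µg/ml, r was 0.709, and 0.656 with the dishes exchanged. The covariance was 0.0435, and 0.00421 in the simulation. Of the 1693 genes called at 20 µg/ml, 1570 were also called at 40 µg/ml. At both doses 749 genes were higher and 820 lower, where independent lists would share 142.3 and 229.8, and treatments simulated with no effect shared 0 in each of 100 simulations. With the PAPC dishes split in the same ways, the lists shared 620 and 548 genes higher and 630 and 656 lower. The simulation leaves out the effects and the independent lists leave out the shared dishes, so that the excess over either is not a measure of a shared effect. A single gene was called in opposite directions. Among the genes called at 40 µg/ml, the median ratio of the log2 difference at 20 to that at 40 was 0.447.

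The series concerns variation between donors, and the donor-by-treatment interaction tested whether the response differed between them. The response of 653 genes differed between donors at an adjusted p below 0.05 in limma (5.62% of those tested), with the spread between dishes as the error, and 462 of these also changed on average at OxPAPC 40. The protease ADAMTS1 had the smallest p, with donor differences between -0.29 and 2.65, followed by THBD with -2.35 to 0.78. The CXCL8 difference ran from 0.13 to 4.01, or from 1.51 to 4.47 in the dimmer probe set, that of HMOX1 from 0.64 to 2.22, and that of the collagenase MMP1 from -0.13 to 1.08. FAM43A (-1.52 to 0.37), DNAJB1 (0.75 to 3.00) and the ATF4 target TRIB3 (-0.48 to 2.81) completed the 8 genes with the smallest p, with an adjusted p between 4.68e-21 and 1.79e-12. In the 7 donors of the larger array number range the mean difference of FAM43A was not below 0. The responses of these 8 genes in the A dishes and in the B dishes correlated over the donors with r between 0.926 and 0.987. Apart from CXCL8, which was to be named in any case, these genes were picked by a test against the spread between dishes. A high r therefore follows from the choice and is no separate evidence.

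CXCL8 levels differed more between donors after PAPC (14.33 ± 1.40 on the log2 scale, SD, n = 12) than after OxPAPC 40 (16.43 ± 0.48). A dimmer CXCL8 probe set gave a larger mean rise, of 3.15 ± 0.95, with levels of 12.08 ± 1.66 after PAPC and 15.24 ± 0.96 after OxPAPC 40. Both probe sets may be compressed at their highest levels, so that the smaller spread after OxPAPC 40 is not read as donors becoming alike. With HMOX1 near the highest value on the arrays after OxPAPC 40, the range of its differences between donors mostly repeats that of its PAPC levels. By Fisher's exact test, the lists enriched for genes with a differing response included the ATF4 targets (16 of 27, adjusted p = 9.09e-13), the immediate early genes (10 of 15, adjusted p = 5.13e-09), the flow-responsive genes (7 of 13, adjusted p = 1.09e-05), the leukocyte-recruiting genes (7 of 15, adjusted p = 2.79e-05) and the heat shock chaperones (5 of 9, adjusted p = 1.73e-04). The SREBP2 targets (6 of 17, adjusted p = 5.59e-04), the NRF2 targets (5 of 19, adjusted p = 0.00638), the VEGF and hypoxia genes (4 of 12, adjusted p = 0.00638), the metallothioneins (3 of 7, adjusted p = 0.00869), the coagulation genes (3 of 11, adjusted p = 0.0312) and the endoplasmic reticulum list (4 of 20, adjusted p = 0.0318) were enriched too. Of the 16 endothelial identity genes 0 differed, and of the 24 cell cycle genes 3 did (adjusted p = 0.187). Fisher's test takes genes as independent, but members of a list varied together. Their estimated correlation was 0.376 for the ATF4 targets and 0.450 for the heat shock chaperones, so that these p-values overstate the evidence. Leaving out 1 of the donors lowered the number of genes to 428, and median scaling of the arrays lowered it by a similar amount.

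**Figure D3:**
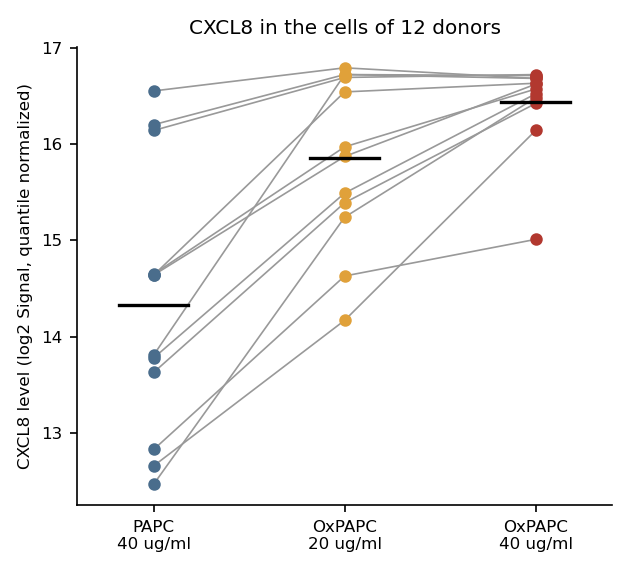
CXCL8 level on the vertical axis (log2 Signal after quantile normalization) under the 3 treatments on the horizontal axis, with 1 point per donor, lines joining the values of a donor and bars at the mean of 12 donors. Levels after PAPC spread from 12.47 to 16.55 and those after OxPAPC 40 µg/ml from 15.01 to 16.72.

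The titles of the OxPAPC samples carry the letter H for 5 donors and L for 7, and the labels used here do not say what the letters mean. The limma fit found 0 genes whose response at OxPAPC 40 differed between the letters at an adjusted p below 0.05, and 339 at an unadjusted p below 0.05, where 581 would be expected by chance. The level after PAPC differed for 0 genes, and for 297 at an unadjusted p below 0.05. The 8 genes with the smallest p were OR1D2, NEDD1, THEMIS2, HOXB-AS1, MIPEPP3, WDFY3-AS2, ZNF404 and PLA2G4C, with an adjusted p of 0.956 or higher. The CXCL8 response in the brighter probe set was 1.86 ± 0.87 (SD, n = 5) in H donors and 2.27 ± 1.44 (n = 7) in L donors (two-sided exact permutation p = 0.563), with levels close together after OxPAPC 40 (16.43 ± 0.48), so that its size is limited. In the dimmer one it was 3.03 ± 0.85 in H donors (n = 5) and 3.24 ± 1.07 in L donors (n = 7, two-sided exact permutation p = 0.713). Over CXCL8 and the mean responses of the 15 lists, the smallest two-sided exact permutation p was 0.205, for the leukocyte-recruiting genes, with 0.50 ± 0.29 in H and 0.31 ± 0.23 in L donors, and the adjusted p was 0.994 for all 16.

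The mean responses of 5 lists were correlated over the 12 donors, in 10 pairs, and 0 pairs passed after Benjamini-Hochberg adjustment. The ATF4 and NRF2 lists gave r = 0.631 (permutation p = 0.0296, adjusted p = 0.195) and rho = 0.622 (permutation p = 0.035), and r = 0.614 without the 2 farthest donors. Within the 7 donors of the larger array number range r was 0.369 (exact permutation, adjusted p = 0.604). The leukocyte-recruiting and ATF4 lists gave r = 0.604 (permutation p = 0.039, adjusted p = 0.195) and rho = 0.35 (permutation p = 0.267), and r = 0.469 without the 2 farthest donors, so that it rests in part on those donors. Within the 7 donors r was 0.722 (exact permutation, adjusted p = 0.604), and the second range holds too few donors for a correlation. The NRF2 and leukocyte-recruiting lists gave r = -0.033 (permutation p = 0.921) and rho = -0.14 (permutation p = 0.667).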

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

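The tests of saturation, the dimmer probe set, the list of LXR targets and the splits between the letters were chosen after the results were seen. A difference between groups drew attention to the 653 genes whose response differed between donors, and a sample far from the others to the VEGF and hypoxia list. Its mean response reached 0.59 in 1 of the 5 H donors, against 0.24 for the next. This was 1 of 32 groups examined, and chance flags about 1 in 20.

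The CXCL8 response ran from 0.13 to 4.01 between donors, and from 1.51 to 4.47 in a dimmer probe set. Noise between dishes is argued against by the A and B dishes, whose responses correlated with r = 0.966 (n = 12 donors). The starting level stays open: the response in either set of dishes fell with the PAPC level in the other, with r = -0.879 (permutation p = 3.1e-04, rho = -0.776, permutation p = 0.00423) and r = -0.956 (permutation p = 2e-05, rho = -0.909, permutation p = 1.2e-04), with -0.778 and -0.922 without the 2 farthest donors, and with -0.909 and -0.935 within the 7 donors of the larger array number range (exact permutation p = 0.00516 and 0.00278), but an r below 0 also follows wherever levels spread less after OxPAPC (SD 0.48) than after PAPC (SD 1.40), and over the 653 genes the medians of these r were -0.349 and -0.344, with CXCL8 8th and 2nd from the lowest. Saturation of the brighter probe set alone is argued against by the dimmer one, with r = -0.798 and -0.847, but saturation of both stays open, since at OxPAPC 20, where the dimmer one is further from the top of its range, r was -0.375 (permutation p = 0.23) and -0.172 (permutation p = 0.592). The array number range cannot be told apart either, since its 7 donors spanned 53.8% of the whole range, with a median of 2.74 against 1.38 in the 4 donors of the second range.

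The cell cycle list was lower at OxPAPC 40 in 23 of 24 members. Scaling is argued against by 23 members lower under both median scaling and the series value table, and the array of low RNA quality by 23 lower without it. A few donors cannot carry it, since the mean was below 0 in 12 of 12. A response of the cells to OxPAPC is a hypothesis that stays open, since other technical explanations were not tested.

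MYLIP (-1.57) and RNF145 (-1.65) were lower and the SREBP2 list higher at OxPAPC 40. Scaling is argued against by falls of at least 1.56 on the log2 scale (differences of -1.56 or lower) under median scaling and in the series value table. Cross-hybridisation is argued against by their other probe sets, at -0.95 or lower. Both genes are known targets of LXR, a sterol-sensing receptor, and lower LXR activity is a candidate explanation that was not decided: over 9 other LXR targets fry gave p = 0.484.

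Exchanging treatments within randomly drawn donors, 1 of 100 splits, the real split, gave as many changed genes in each comparison. That is the smallest share that 100 splits can give, so that it argues against chance but cannot exclude it. The real counts were 5067 at OxPAPC 40, 1693 at OxPAPC 20 and 2505 between the doses, and the highest of the other splits gave 3156, 247 and 842. A split with few or nearly all donors exchanged would keep much of the real difference. These highest counts are therefore not read as a level that chance gives. For the letters H and L, 91 of 100 splits gave at least as many genes as the 339 for the response (highest other 1164), and 86 of 100 as many as the 297 for the PAPC level (highest other 2014), so that chance cannot be excluded. The highest splits, with several times the real count, point to a structure of the donors or to genes that vary together, and neither was tested.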

How the results depend on the processing

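The largest offset and the fit without the PAPC array of low RNA quality were chosen after seeing the data. The counts below moved by over 1.5 times under these settings, apart from the 13 lists called at OxPAPC 40. The cause was not tested. Where fewer donors, dishes or genes entered, the effect of the smaller number was not told apart from other causes. Median scaling gave 485 genes lower at OxPAPC 20, 701 higher at OxPAPC 40 against 20, and 424 whose response differed between donors. Without the replicate block of donor, 951 genes were higher and 1047 lower at OxPAPC 40, 104 and 41 at OxPAPC 20, and 222 and 160 between the doses. The A dishes alone gave 506 higher at OxPAPC 20 and 521 higher and 516 lower between the doses, and the B dishes alone 531 higher and 479 lower at OxPAPC 20. The interaction could not be computed from single dishes. The 7 donors of the larger array number range gave 497 higher and 457 lower at OxPAPC 20, and 218 genes whose response differed. The 4 donors of the second range gave 957 higher and 1355 lower at OxPAPC 40, 139 and 113 at OxPAPC 20, 134 and 98 between the doses, and 62 genes whose response differed. The correlation between the doses, r = 0.82 over all donors, was 0.748 in these 4 and 0.664 with no filter. Both moved by more than the SD of this correlation over donors (0.065), the measure used for it in place of 1.5 times. A filter of Present on 60 of 72 arrays gave 18 genes changed at least 2-fold at OxPAPC 20 and 1 correlated pair of lists, and the largest offset gave 13 genes changed at least 2-fold between the doses. Of the lists, camera called 10 at OxPAPC 40 and 9 between the doses, and with an estimated correlation 2 and 3. At OxPAPC 40 the leukocyte-recruiting, flow-responsive and Notch lists were gained under median scaling, with no filter and in the A dishes, for 13 called in each. Fry called 14 between the doses.

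Leaving out each donor in turn gave 10 to 13 lists called at OxPAPC 40, 1915 to 2066 genes higher and 2776 to 2998 lower at OxPAPC 40, 687 to 837 and 725 to 948 at OxPAPC 20, and 918 to 1072 and 1186 to 1420 between the doses. Genes changed at least 2-fold numbered 153 to 169, 28 to 32 and 20 to 28. The response differed between donors for 428 to 725 genes, the lowest without 1 donor, and the PAPC level differed between the letters for 0 to 1. Without the array of low RNA quality no count moved by over 1.5 times.

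Of 8727 values of named genes under the alternatives, 8240 kept their side of the threshold, 418 fell short, 61 newly passed and 8 reversed, none past the threshold there. A change of sign was counted as reversed only where the main fit or the alternative passed the threshold. Changes of sign past the threshold in neither fit are among the 8240 and were not counted. With the mean of probe sets ENG (0.051 at OxPAPC 40, 0.0026 between the doses) and ROBO4 (0.00414) reversed, which follows from their second probe sets. LYVE1 (-0.12) reversed in the A dishes, FAM43A (8.3e-05) in the 7 donors, and PLAT (0.093 at OxPAPC 40, 0.0016 at OxPAPC 20) and GJA5 (0.18 between the doses) in the 4 donors. The number of arrays, not sequencing depth, limits precision, and genes called Absent on most arrays lie near background.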

Other observations

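The test of CXCL8 against the ATF4 list was chosen after the result was seen, as was the list of LXR targets. Among 9 tested LXR targets other than MYLIP, the cholesterol exporter ABCA1 was lower at OxPAPC 40 (-0.80 ± 0.12, SE, lower in 12 of 12 donors, limma adjusted p = 2.96e-06) and at OxPAPC 20 (-0.57). The fatty acid desaturase SCD was higher at OxPAPC 40 (0.33 ± 0.06, higher in 11 of 12 donors, adjusted p = 7.31e-05). The cholesterol exporter ABCG1 (0.04) and the regulator SREBF1 (-0.14) did not pass the test.

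ZNF792 stood among the largest falls from OxPAPC 20 to OxPAPC 40, although ZNF442 stood among the largest rises at OxPAPC 20, and the hypothesis that zinc finger genes fell as a class was tested on OxPAPC 40 against PAPC. Over the 368 other ZNF genes tested, the median log2 difference at OxPAPC 40 was -0.030, at the 17.9th percentile of 10000 random lists matched on mean level, which argues against a fall of the class. Of these genes 94 were lower and 52 higher.

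The CXCL8 response may vary jointly with that of the ATF4 targets. With CXCL8 from the A dishes and the list from the B dishes r was 0.675 (permutation p = 0.0161, rho = 0.559, permutation p = 0.0626), and with the dishes exchanged r was 0.701 (permutation p = 0.0119, rho = 0.65, permutation p = 0.0263). With both dishes r was 0.748 (permutation p = 0.00529, rho = 0.72, permutation p = 0.0112), 0.512 without the 2 farthest donors, and 0.455 within the 7 donors of the larger array number range (exact permutation p = 0.298). The relation thus rests in part on those 2 donors, and it is open to the compression of CXCL8 at its highest levels.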
